A study of Mus musculus with 2 samples.

How the data were processed

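Large intestine epithelium from Neurod1-Cre x EYFP mice, in which cells of the enteroendocrine lineage carry a fluorescent reporter, was digested with collagenase and sorted for reporter-positive cells. The mice had free access to chow and were killed fed, in the light phase. Per the labels, 2 samples of 3500 cells each were loaded on a 10x Genomics Chromium instrument with the 3' v2 chemistry. The series text gives 3500 collected cells without saying whether this is per sample, so the loaded total of 7000 rests on the sample labels. It does not state how many mice were pooled.

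The deposited table holds raw UMI counts per gene and cell barcode, unnormalised. Cell Ranger 2.0.0 and Seurat 2.0, with genome build mm10, are named in the submitters' processing notes. How barcodes were chosen and how both samples were joined is not stated. The 1779 barcodes carry a single suffix, which does not show that both samples are in the table, and no cell could be assigned to either sample. The table was therefore treated as 1 pooled sample, and the planned tests with each sample as a replicate, the agreement of both samples and their separate class shares were not computed. No p-value is given. Intervals on levels, ratios and shares cover counting error alone, not differences between mice or samples.

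The table lists 27998 Ensembl gene identifiers, of which 27645 were matched to a symbol in GENCODE M21 and 353 were not. A symbol was shared by several identifiers in 8 cases. Coordinates come from the same GENCODE release on GRCm38, which may differ from the annotation used by the submitters.

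Cells were kept with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs, and genes with a UMI in at least 3 cells. Of the 1779 barcodes, 2 had too few genes, none too few UMIs and 34 too much mitochondrial RNA. Scrublet, as in scanpy, with an expected rate of 0.03, called 8 of the 1743 remaining cells (0.459%) doublets, which were left out. This left 1735 cells and 11219614 UMIs.

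For clustering, counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen after removal of the 253 genes of the 8 readout lists. Leiden clusters were computed from 30 principal components and 15 exact neighbours at resolution 0.8 with seed 0. The readout lists hold nutrient and metabolite receptors, neurohormonal receptors, ion channels, nutrient and ion transporters, lineage transcription factors, Hox positional genes, genes of granules and exocytosis, and genes of amine synthesis and handling. The remaining lists are peptide hormones, pan-enteroendocrine genes, dissociation stress, cell cycle and the markers of 16 cell types, 28 lists in all.

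The lists and comparisons, the rule for named genes and the first set of alternatives were fixed before the data were examined. The score that turned markers into cluster names was set after the clusters had been seen. Each cluster's level, plus 50 CPM, was set against the 25th percentile of the other clusters. A cluster was placed outside the enteroendocrine classes when at least 50% of another cell type's markers were raised at least 2-fold with a UMI in at least 20% of its cells. It kept that type's name unless another type had more markers among its 10 leading genes. Otherwise it took the enteroendocrine class with the highest mean log2 fold. Names end in "-like" because they rest on transcripts alone.

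UMIs were summed over the cells of a class and expressed as counts per 1000000 UMIs of that class (CPM). Levels and ratios carry exact 95% intervals, Poisson for a level and binomial for the ratio of 2 counts. Ratios against a class with 0 UMIs were computed against a floor of 3 UMIs and are lower limits. A gene of the fixed lists was named when its ratio was at least 4 in either direction, with at least 30 UMIs in the higher class and a UMI in at least 5% of its cells, up to 4 genes per list in order of ratio. Outside the lists, the 8 genes with the largest ratio on each side were named among those with at least 100 UMIs and a UMI in at least 20% of the cells of the higher class. Some genes that meet this rule are not listed by name. Counts of list genes past this rule describe size and are not test results. For each readout list, the median log2 ratio of members with at least 10 UMIs was placed among 10000 random lists of like size and expression, drawn within 20 expression bins. The percentile is a description.

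For hormone co-detection, cells were thinned to 2000 UMIs without replacement, and a cell was positive at 5 UMIs. Since this planned threshold turned out to lie within the free RNA background of Gcg and Pyy, a second one was added after the data had been seen. It is the smallest count, of at least 5, that a Poisson variable reaches with a probability under 0.001. The variable was set at 3 times the mean of a class lacking the hormone, with 10% of cells trimmed at each end of that mean. Shares carry exact Clopper-Pearson 95% intervals.

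On simulated counts, 100% of 100 genes changed 8-fold and 0 of 12599 unchanged genes passed the size rule, and 96.2% of 12799 intervals held the true ratio. All 8 unchanged lists fell between percentiles 1 and 99. Of 1735 cells simulated from the cluster means, 98.5% returned to their class. The grouping of cells itself was recovered (adjusted Rand index 1.0), so the rest changed class through the naming. These simulated cells differ within a cluster or class only by depth and counting, and the clusters were those already found. Their return therefore says little about how distinct the real clusters are, and the interval check covers counting error alone.

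Alternatives were resolutions of 0.4 and 1.6, 15 principal components, variable genes with the readout lists, every barcode, a stricter filter at 1000 genes and 3000 UMIs, and doublets kept. Clusters and levels were also taken from separate random portions of the UMIs. Ratios were recomputed with scaling that left out hormone, granule, marker and the 50 most abundant genes, with no minimum on UMIs and as means over cells. Co-detection was recomputed at other depths and thresholds. Chosen after seeing the data were a comparison that joins both Insl5-high clusters and the background thresholds at 3 and 5 times the mean. The co-detection pairs followed across the alternatives were also chosen after their values were seen. These pairs are Gcg among Insl5 cells, Insl5 among Gcg cells and Nts among Insl5 cells.

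The computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0 and igraph 0.11.9. Figures were drawn with matplotlib 3.10.9.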

Results

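The data are single-cell transcriptomes of reporter-positive enteroendocrine cells from the mouse large intestine, in 1 group of 2 samples without treatment. The series set out to profile these cells one by one, and the comparisons below ask which classes of hormone cell they form and which receptors, channels, transporters and granule genes each class carries. The table held 11459276 UMIs in 1779 barcodes, and 17621 genes had a UMI. The barcodes are 25.4% of the 7000 cells loaded, if both samples are in the table. A barcode held 1926 to 47042 UMIs, with a median of 5134, and a median of 2099 genes. The median share of mitochondrial UMIs was 3.53%. After filtering, 1735 cells with a median of 5162 UMIs and 2118 genes remained. As cells cannot be assigned to a sample, there are no replicates behind any value.

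Hormone transcripts took a large part of the RNA. Pyy, encoding peptide YY, made up 6.26% of all kept UMIs, Gcg, encoding proglucagon, 2.26%, Chgb 1.04%, Chga 0.79% and Insl5, a peptide of the relaxin family, 0.691%. Pyy and Gcg had a UMI in 100% of kept cells, including cells of non-endocrine clusters, which is the trace of free RNA in the droplets. In the EC-like class the mean was 21.6 Pyy and 5.25 Gcg UMIs among 2000, and hormone co-detection was read against this background. The ratios between classes are of levels with the background left in.

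The cells formed 14 clusters. EC-like cells, named for serotonin-producing enterochromaffin cells, made up 757 of 1735 cells (43.6%, 41.3 to 46.0). L-like cells, which express Gcg, Pyy and Insl5, numbered 642 (37.0%, 34.7 to 39.3). D-like cells, which express somatostatin, numbered 166 (9.57%, 8.22 to 11.1). Together these classes held 1565 cells, or 90.2%. No cluster was named K-like, X-like or progenitor-like, but the smallest cluster held 13 cells, so scattered cells of these types are not excluded. Single cells that express Ghrl lay mostly within the L-like class. The median depth was 7820 UMIs in L-like, 3883 in EC-like and 4500 in D-like cells.

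The 170 cells outside the enteroendocrine classes (9.80%, 8.44 to 11.3) had a median of 13631 UMIs. A goblet-like cluster held 31 of them (1.79%), with Muc2, the main secreted mucin, at 8349 UMIs per 1000000 UMIs (CPM). A stromal-like cluster held 13 (0.749%), with Col1a1 at 604 CPM. The remaining 126 (7.26%) formed an unnamed cluster that carried Car1, a colonocyte carbonic anhydrase, at 2281 CPM together with Jchain at 1592 and Cd74 at 398, genes of antibody-secreting and antigen-presenting cells.

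**Figure D1:**
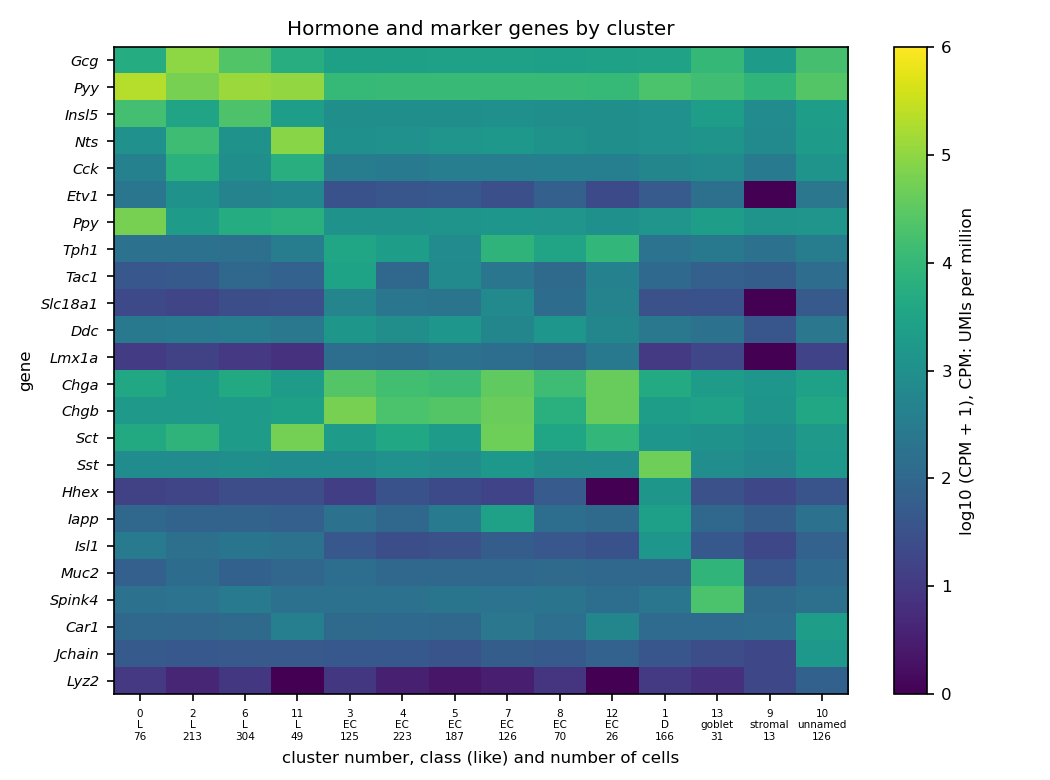
Levels of hormone and marker genes (rows) in the 14 clusters (columns, with cluster number, class and number of cells), as log10 of CPM plus 1, with no error shown. Gcg reaches 95592 CPM in L-like cluster 2, Nts 86142 in cluster 11 and Ppy 57942 in cluster 0, while Pyy is at 8476 or more in every cluster.

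The first comparison set EC-like against L-like cells, the 2 main classes. EC-like cells carried 17.7-fold more Tph1 (16.5 to 18.9), the rate-limiting enzyme of gut serotonin synthesis, at 3214 against 182 CPM. Slc18a1, a vesicular monoamine transporter, was 15.2-fold higher (12.5 to 18.6), and Tac1, the precursor of substance P, 11.3-fold. Lmx1a, a transcription factor of enterochromaffin cells, stood at 152 against 10.1 CPM. In L-like cells Gcg was 15.8-fold higher (15.4 to 16.1), Insl5 13.9-fold, Pyy 10.6-fold and the transcription factor Etv1 16.2-fold. Of these genes, all but Insl5 had entered the clustering, so these ratios describe the classes rather than test them. Gcg in EC-like cells, at 2613 CPM, lay near its level in D-like cells, 2923, and in the stromal-like cluster, 2065, as free RNA would.

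Nutrient and metabolite receptors leaned to L-like cells. Of 13 measured members, 5 were at least 4-fold higher in L-like and 1 in EC-like cells, and the list median was -1.77 on the log2 scale (counting interval -2.29 to -1.26), at percentile 0 of random lists. Ffar1, a receptor for long-chain fatty acids, was 13.2-fold higher in L-like cells (8.24 to 22.5). Gpr119, a receptor for fatty acid amides and monoacylglycerols, was 11.1-fold higher (8.49 to 14.8), and Sucnr1, the succinate receptor, 13.1-fold on 2 UMIs in EC-like cells (3.42 to 112). After thinning to 2000 UMIs, Gpr119 had a UMI in 32.1% of L-like and 3.35% of EC-like cells. Olfr558, an olfactory receptor that responds to branched short-chain fatty acids, went the other way and was 43.5-fold higher in EC-like cells (20.7 to 110). Without a minimum on UMIs the list median was -0.54.

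Receptors for hormones and transmitters divided between the classes. Of 25 measured, 4 were at least 4-fold higher in EC-like and 3 in L-like cells, with a median of 0.71 at percentile 98.7 but a counting interval from -0.07 to 0.79. Npy1r, a receptor for neuropeptide Y, was 19.8-fold higher in EC-like cells (10.7 to 40.6) and Vipr2, a receptor for vasoactive intestinal peptide, 11.8-fold (6.60 to 23.1). Within the EC-like class, Vipr2 stood at 45.7 CPM in clusters 4, 5 and 8 but at 4.395 on 5 UMIs in clusters 3, 7 and 12. In L-like cells it stood at 2.48 CPM in clusters 0 and 6 and at 2.74 in clusters 2 and 11. Agtr1a, the angiotensin receptor, was 10.6-fold higher in L-like cells (8.10 to 14.2) and Avpr1b, a vasopressin receptor, 10.4-fold (7.25 to 15.5). Within the L-like class, Agtr1a stood at 287 CPM in clusters 0 and 6 and at 17.0 in the other clusters, against 17.8 in EC-like cells. Avpr1b stood at 148 and 28.5 CPM in the same order, against 10.05 in EC-like cells.

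Ion channels leaned to EC-like cells. Of 34 measured, 4 were at least 4-fold higher there and 2 in L-like cells, and the median was 0.78 (0.58 to 1.08), at percentile 100. Piezo2, a mechanically gated channel, was 16.3-fold higher (12.9 to 20.8) and had a UMI in 34.9% of EC-like and 2.83% of L-like cells at 2000 UMIs. Trpm2, a calcium-permeable cation channel, was 7.56-fold higher, Itpr3, a calcium release channel of the endoplasmic reticulum, 5.84-fold and Kcnq1, a potassium channel, 5.43-fold.

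Among 19 measured transporters, 1 was higher in EC-like and 3 in L-like cells. Slc38a11, a putative amino acid transporter, was 37.3-fold higher in EC-like cells (27.2 to 52.5), at 295 against 7.92 CPM. The fructose transporter Slc2a5 was 6.27-fold higher in L-like cells, the sodium-glucose cotransporter Slc5a1 4.86-fold and Slc51b, a subunit of a bile acid exporter, 4.64-fold (1.82 to 15.1). The list median of 0.13, at percentile 12.4, had an interval across 0 (-0.81 to 0.25), and the list mean had the opposite sign, -0.23.

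Of 30 measured lineage transcription factors, 1 was higher in EC-like and 2 in L-like cells, with a median of 0.49 (0.36 to 0.67) at percentile 99.5. Isl1, a factor of endocrine differentiation, was 5.49-fold higher in L-like cells (4.52 to 6.74), while Sox9 was 4.08-fold higher in EC-like cells (2.84 to 5.95). None of 25 Hox genes passed the size rule between the classes, with a list median of 0.56 (0.32 to 0.79) at percentile 97.1.

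Granule genes differed in both directions. Of 33 measured, 6 were at least 4-fold higher in EC-like and 2 in L-like cells, with a median of 0.34 (0.26 to 0.49) at percentile 90.2. Chgb, a chromogranin that packs secretory granules, stood at 31440 CPM in EC-like and 1865 in L-like cells, 16.9-fold apart (16.5 to 17.2), and Chga was 5.91-fold higher in EC-like cells. Rab3c and Rab3b, small GTPases of secretory vesicles, were 17.7-fold and 13.9-fold higher, whereas the granin Scg2 was 14.4-fold higher in L-like cells (12.2 to 17.0). Among 8 measured genes of amine handling, 1 passed the rule, Maob, a monoamine oxidase, 4.08-fold higher in EC-like cells (2.98 to 5.65), and the list median was 1.17 (1.03 to 1.30) at percentile 100. Across the 187 measured genes of the 8 lists the median was 0.46 (0.35 to 0.54) at percentile 100, against 0.32 for all 12825 genes.

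**Figure D2:**
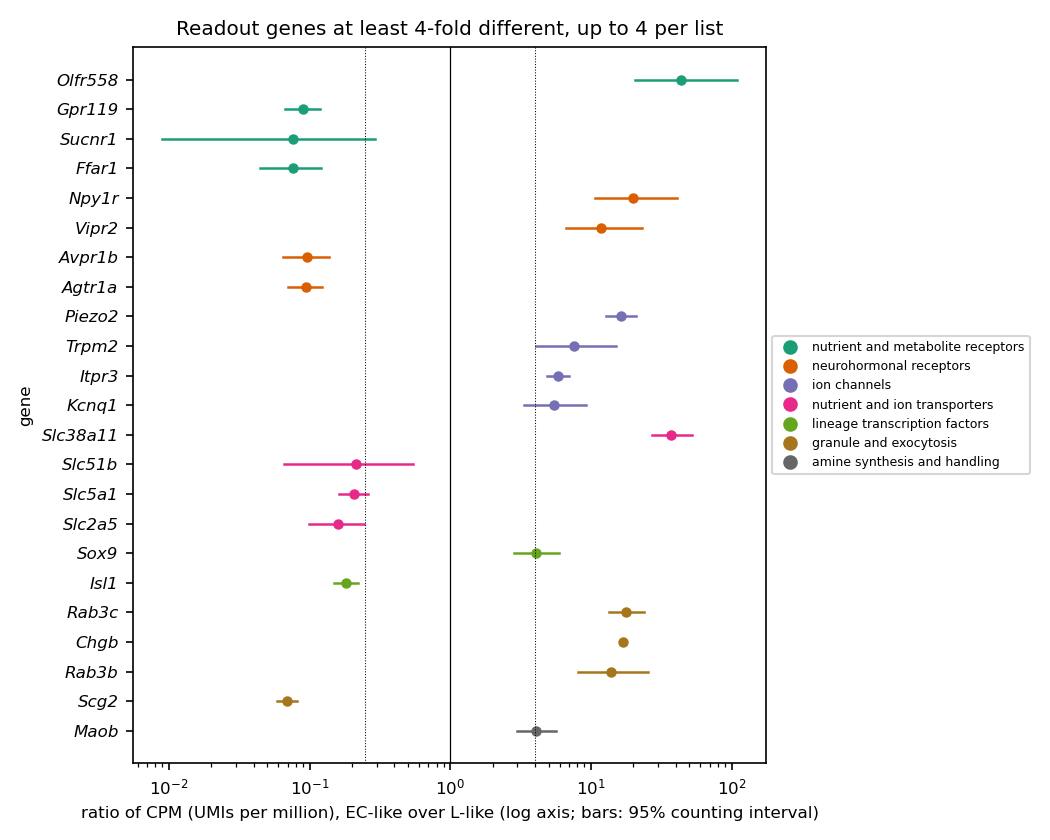
Ratio of CPM in EC-like over L-like cells (x axis, logarithmic) for readout genes named in the text (y axis), coloured by list, with 95% counting intervals as bars and dotted lines at a 4-fold difference. Olfr558 (43.5) and Slc38a11 (37.3) lie farthest to the EC-like side, and Scg2, Ffar1 and Sucnr1 at ratios of 0.0696 to 0.0762 on the L-like side.

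Of 19 measured peptide hormones, 4 were at least 4-fold higher in EC-like and 7 in L-like cells. Nmb, encoding neuromedin B, was 14.1-fold higher in EC-like cells on 43 against 5 UMIs (5.59 to 45.6), and Iapp, encoding amylin, 6.77-fold higher (6.08 to 7.56). Ghrl, encoding ghrelin, was 7.05-fold higher in L-like cells (6.02 to 8.30). Of 11 pan-enteroendocrine genes, 2 passed the rule on each side.

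Few markers of other cells passed the size rule. Of 8 colonocyte markers 1 passed, Krt20, a keratin of differentiated epithelium, 4.67-fold higher in EC-like cells, with a list median of 0.29. Of 4 measured progenitor markers 1 passed, Sox4, 4.62-fold higher in EC-like cells, with a median of 1.43. No marker passed the rule among those of goblet cells (6 measured, median 0.29), stem or transit-amplifying cells (6, 0.37), tuft cells (5, -0.14), myeloid cells (5, -0.10), lymphocytes (2, 1.73), stromal cells (3, 3.88), or, with 1 measured gene each, of endothelium (1.10), glia (2.01) and enteric neurons (1.10). The K-like marker measured, Fabp5, did not pass (-1.92). Of the L-like markers 5 of 5 and of the X-like 1 of 3 were higher in L-like cells, with medians of -3.80 and -2.61, and of the EC-like markers 4 of 6 and of the D-like 1 of 3 were higher in EC-like cells, with medians of 3.71 and 0.19. The stromal-like median rests on few UMIs, such as 25 against 5 for Dcn. None of 16 dissociation stress genes and none of 12 cell cycle genes passed, with medians of -0.26 and 0.43.

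Outside the lists, genes with a large ratio towards EC-like cells were Fam19a1 (25.0-fold), Cwh43 (22.9-fold), Cntn4, a neuronal adhesion protein (18.1-fold), and Plet1, Tmigd3, Ceacam20 and Tmem158 (17.9-fold to 12.8-fold). Towards L-like cells they were Ntng1, a netrin (32.4-fold on 3 UMIs in EC-like cells, 10.9 to 159), 2010106E10Rik (15.7-fold), Cyp4x1 and its antisense transcript Cyp4x1os (11.5-fold and 11.3-fold), Syndig1, Ms4a5, Rtbdn, and Ppy, encoding pancreatic polypeptide (9.17-fold). Among these genes, Cntn4, Plet1, Tmem158, Ms4a5 and Ppy had entered the clustering, while 2010106E10Rik and Syndig1 had not. Over all lists, 27 genes passed the size rule towards EC-like and 25 towards L-like cells. The all-gene median log2 ratio fell from 0.32 to 0.12 when scaling left out hormone, granule, marker and abundant genes, so list medians are read against it. EC-like cells were the shallower class, and the ratios rest on summed UMIs, 3085639 in EC-like and 5053520 in L-like cells.

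The second comparison set D-like against L-like cells. Sst, encoding somatostatin, was 53.9-fold higher in D-like cells (52.2 to 55.6), at 48260 CPM, and Hhex, a transcription factor of somatostatin cells, 69.0-fold (56.5 to 84.9). Iapp was 29.0-fold higher (26.0 to 32.3). Gcg was 14.1-fold higher in L-like cells, Insl5 12.6-fold, Etv1 12.6-fold and Nts, encoding neurotensin, 9.54-fold. All of these but Insl5 had entered the clustering. Of 17 measured peptide hormones, 2 were at least 4-fold higher in D-like and 6 in L-like cells.

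Receptors set the classes apart in both directions. Calcrl, the calcitonin receptor-like receptor that binds calcitonin gene-related peptide and adrenomedullin with its partner proteins, was 78.1-fold higher in D-like cells on 46 against 4 UMIs (28.5 to 299). Adra2a, an adrenergic receptor, was 25.1-fold higher (12.2 to 56.6). Of 25 measured neurohormonal receptors, 2 were at least 4-fold higher in D-like and 5 in L-like cells, with a median of -0.04 at percentile 6.1. Avpr1a, a vasopressin receptor, had 0 UMIs in D-like cells and was at least 6.48-fold higher in L-like cells, and Sstr1, a somatostatin receptor, was 8.54-fold higher on 1 UMI in D-like cells (1.47 to 343). Of 12 measured nutrient receptors, 4 were higher in L-like and 0 in D-like cells, with a median of -1.01 at percentile 0. These were Ffar1 (28.7-fold on 2 UMIs, 7.88 to 238), the bile acid receptor Gpbar1 (12.2-fold on 3 UMIs, 4.14 to 59.7), Gpr119 (6.53-fold, 4.33 to 10.3) and Olfr78, a receptor for short-chain fatty acids (4.73-fold, 2.93 to 8.18). The Olfr78 ratio rests mainly on L-like clusters 0 and 6, at 154 CPM. In the other L-like clusters Olfr78 stood at 26.3 CPM, near the 22.8 of D-like cells. Avpr1a and Sstr1 stood at 39.4 and 16.7 CPM in clusters 0 and 6. In the other L-like clusters they stood at 2.74 and 2.19 CPM, against 0 and 1.34 in D-like cells. Ffar1 was above its D-like level of 2.69 CPM in both sets of L-like clusters, at 31.9 and 157.

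Among transcription factors, 3 of 29 were higher in D-like cells, with a median of 0.34 at percentile 75.5. Sox9 was 10.7-fold (7.22 to 16.1), Isl1 7.06-fold and Nr1d1, a clock repressor, 4.95-fold higher in D-like cells. Of 23 measured Hox genes, 4 were higher in L-like and 0 in D-like cells, with a median of -0.74 at percentile 0. They were Hoxb8 (9.30-fold, 5.41 to 17.6), Hoxb7 (4.89-fold), and Hoxb4 and Hoxb3 on 1 UMI each in D-like cells (16.9-fold, 2.98 to 675, and 11.3-fold, 1.98 to 454). These ratios rest mainly on L-like clusters 2 and 11. In L-like clusters 0 and 6 (380 cells) Hoxb8 stood at 24.2 and Hoxb7 at 10.85 CPM, against 17.5 and 13.4 in D-like cells. Hoxb4 and Hoxb3 stood at 2.48 and 2.79 CPM there, against 1.34 each in D-like cells.

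Piezo2 was 8.27-fold higher in D-like cells (6.06 to 11.3), the 1 of 31 ion channels past the rule, with a median of 0.59 at percentile 99.2. Slc15a1, the oligopeptide transporter, was 10.9-fold higher in L-like cells (4.63 to 33.8), the 1 of 18 transporters, with a median of 0.51 at percentile 90.9. Scg2 was 7.92-fold higher in L-like cells, the 1 of 33 granule genes, with a median of 0.16 at percentile 15.9. Its ratio rests mainly on L-like clusters 0 and 6, at 1016 CPM against 176 in clusters 2 and 11. Gch1, which starts the synthesis of tetrahydrobiopterin, was 4.16-fold higher in D-like cells (3.58 to 4.83), the 1 of 8 amine genes, with a median of 0.05 at percentile 15.6. The X-like marker Mboat4, the acyltransferase that modifies ghrelin, was 7.44-fold higher in D-like cells, and the K-like marker Fabp5, a fatty acid binding protein, 4.65-fold higher in L-like cells. The stress list had a median of 0.69, with 1 of 16 members past the rule, Nr4a1, 6.31-fold higher in D-like cells, and the 8 measured cell cycle genes a median of 0.61.

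Outside the lists, Olfml3 (91.0-fold), Igfbp7 (37.8-fold), Gria2, a glutamate receptor subunit (31.9-fold), Stxbp5l (22.5-fold), Lgals2 (16.3-fold), Rbp4, the retinol carrier (12.0-fold), Nrp2, a semaphorin receptor (8.13-fold), and Cd24a (6.69-fold) had the largest ratios towards D-like cells. At least Olfml3, Igfbp7, Gria2 and Rbp4 had entered the clustering. The largest ratios towards L-like cells were those of Cyp4x1 (2 against 544 UMIs), Crybb1, Fap, Negr1, Atp10b (15.2-fold), Gm5424, the drug exporter Abcb1a (11.9-fold) and Cyp4x1os, at least 11.8-fold with 0 UMIs in D-like cells. Over all lists, 11 genes passed the rule towards D-like and 24 towards L-like cells. The D-like class held 744537 UMIs, so many L-like genes rest on a few D-like UMIs, and the all-gene median moved from 0.28 to 0.05 with the other scaling, a difference larger than the granule and amine medians.

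The third comparison asked how the clusters of Gcg and Pyy cells differ, by setting the L-like cluster with the highest Insl5 level (cluster 6, 304 cells, 20537 CPM) against the remaining 338 L-like cells in clusters 0, 2 and 11. Cluster 6 had 16.3-fold less Nts (15.7 to 16.9), 6.45-fold less Sct, encoding secretin, and 5.0-fold less Cck, encoding cholecystokinin. Nts and Sct had entered the clustering, so their ratios describe the clusters rather than test them. Avpr1a was 8.35-fold higher (4.78 to 15.7) and Mc4r, a melanocortin receptor, 5.55-fold (2.80 to 12.2), the 2 of 21 neurohormonal receptors past the rule, and the list median was 0.79 at percentile 100.

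Hox genes separated these clusters. Of 23 measured, 2 were at least 4-fold higher in cluster 6 and 7 in the other clusters, with a median of -0.71 at percentile 0. Hoxb2 was 23.2-fold lower in cluster 6 on 3 UMIs (7.62 to 115), Hoxb5 19.2-fold on 2 UMIs (4.96 to 164), Hoxb4 15.6-fold (7.31 to 39.7) and Hoxb7 11.4-fold (7.68 to 17.6). The caudal factor Cdx2, which patterns the intestine, was 5.86-fold lower (4.40 to 7.93), the 1 of 29 transcription factors past the rule, with a list median of 0.01. Kcnmb2, a subunit of calcium-activated potassium channels, was 4.40-fold higher (3.52 to 5.54), the 1 of 30 ion channels, with a median of -0.01. Sucnr1 was 7.67-fold lower (3.02 to 25.0), the 1 of 11 nutrient receptors, with a median of 0.28. None of 18 transporters, 32 granule genes or 7 amine genes passed, with medians of 0.18, 0.32 and -0.01.

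Fabp5 was 5.21-fold higher in cluster 6, and C1qa, a myeloid marker, 5.22-fold lower on 6 against 31 UMIs (2.14 to 15.3). None of 16 stress genes or 8 cell cycle genes passed, with medians of 0.51 and -0.22. Outside the lists, Igfbp3, which binds insulin-like growth factors, was 16.4-fold higher (10.3 to 27.6), followed by Acsl6 (4.91-fold), Ramp1, a partner protein of the calcitonin receptor-like receptor (4.23-fold), 1600014C10Rik, Pde1b, Rbpms, Col8a1 and Prss12 (4.16-fold to 3.86-fold). Mal (39.0-fold), Gm11992, Vim, an intermediate filament protein (16.3-fold), Hoxb5os, the neurotrophin Bdnf (12.6-fold), Osr2, Ms4a5 and Thbs1 (8.70-fold) were lower in cluster 6. Among these genes, Igfbp3, Mal, Vim and Ms4a5 had entered the clustering, while Pde1b, Prss12, Gm11992 and Bdnf had not.

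In all, 6 list genes were at least 4-fold higher in cluster 6 and 13 in the other clusters. The first of these counts depends on which clusters are joined. With the other Insl5-high cluster (cluster 0, 15810 CPM) added to cluster 6, 17 genes passed, and at resolution 1.6 it was 0, with Mc4r then at -0.53 on the log2 scale. In the joined comparison, chosen after seeing the data, Agtr1a was 16.9-fold higher in the Insl5-high clusters (11.8 to 25.1), Kcnmb2 19.4-fold, Avpr1a 14.4-fold, the monocarboxylate transporter Slc5a8 6.89-fold and Olfr78 5.87-fold. Nts was 22.6-fold, Cck 7.66-fold, Ffar1 4.91-fold and Gcg 4.13-fold lower there. Of these, Nts and Gcg had entered the clustering and Ffar1 had not.

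**Figure D3:**
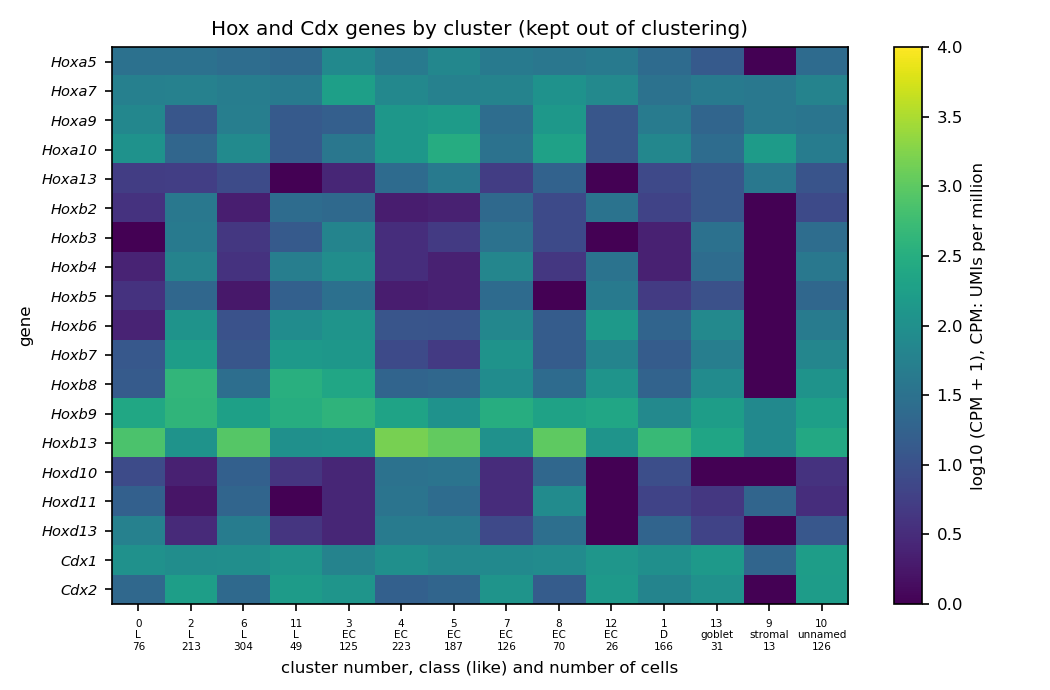
Levels of Hox and caudal genes (rows), none of which entered the clustering, in the 14 clusters (columns, with number, class and number of cells), as log10 of CPM plus 1, with no error shown. Hoxb13 stands at 743 and 867 CPM in L-like clusters 0 and 6 and at 112 and 100 in clusters 2 and 11, and EC-like clusters 4, 5 and 8 stand above 3, 7 and 12 (gene chosen after its values were seen).

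Co-detection of hormones was read cell by cell in 1714 cells thinned to 2000 UMIs, without clusters. At the planned threshold of 5 UMIs, 550 of 588 Insl5-positive cells were also Gcg-positive (93.5%, 91.2 to 95.4), but so were 64.7% of Insl5-negative cells. Of the Gcg-positive cells, 43.0% were Insl5-positive (40.3 to 45.8), against 8.74% of Gcg-negative cells, and of the Insl5-positive cells 24.0% were Nts-positive (20.6 to 27.6), against 19.1% of Insl5-negative cells. Pyy passed 5 UMIs in all 1714 cells and Gcg in 1279 (74.6%), and 223 of 352 Tph1-positive (63.4%) and 128 of 210 Sst-positive cells were Gcg-positive. The background of these hormones thus lies at or near the planned threshold, which was replaced by 30 UMIs for Gcg, 92 for Pyy, 15 for Insl5, 17 for Nts, 8 for Cck, 13 for Sst and 18 for Sct.

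Above background, Insl5 was found in 347 cells, of which 337 also expressed Pyy (97.1%, 94.8 to 98.6) and 181 Gcg (52.2%, 46.8 to 57.5). Insl5 and Nts rarely passed together, with 4 of 347 Insl5 cells positive for Nts (1.15%, 0.315 to 2.93) against 9.44% of the cells without Insl5. Cck was found in 209 cells, of which 185 expressed Gcg (88.5%, 83.4 to 92.5) and 78 Nts (37.3%, 30.8 to 44.3). Of 133 Nts cells, 61 expressed Sct (45.9%, 37.2 to 54.7). None of 156 Sst cells passed the Gcg threshold, and the interval reaches 2.34%. Tac1 was found in 73 cells, of which 29 expressed Tph1 (39.7%, 28.5 to 51.9), while of 352 Tph1 cells 37.8% expressed Sct. Ghrl was found in 17 cells and Gip, the K-cell hormone, in none of 1714.

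By class, Gcg exceeded background in 59.2% of 635 thinned L-like cells (55.3 to 63.1), Pyy in 77.2%, Insl5 in 53.4%, Cck in 30.4% and Nts in 19.7%. Tph1 did so in 46.0% of 746 EC-like cells (42.4 to 49.6), Sct in 19.0% and Tac1 in 9.79%. Sst did so in 88.6% of 166 D-like cells (82.7 to 93.0) and Iapp in 27.7%. Gcg passed in 0 of 746 EC-like cells, with an interval up to 0.493%, but these cells had set the threshold. In D-like cells, which had not, it was 0 of 166, with an interval up to 2.20%. Counted over combinations of Gcg, Pyy, Insl5, Nts, Cck, Sst and Tph1 alone, 519 cells (30.3%) passed for none of them, 157 for Pyy and Insl5, 146 for Gcg, Pyy and Insl5, and 72 for Gcg and Cck. Cells that express a hormone below the raised thresholds count as negative. The shares of each class above background are therefore low estimates, and the 30.3% that passed for none is a high one. Combinations that lack a hormone, such as Pyy and Insl5 without Gcg, can gain or lose cells this way.

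**Figure D4:**
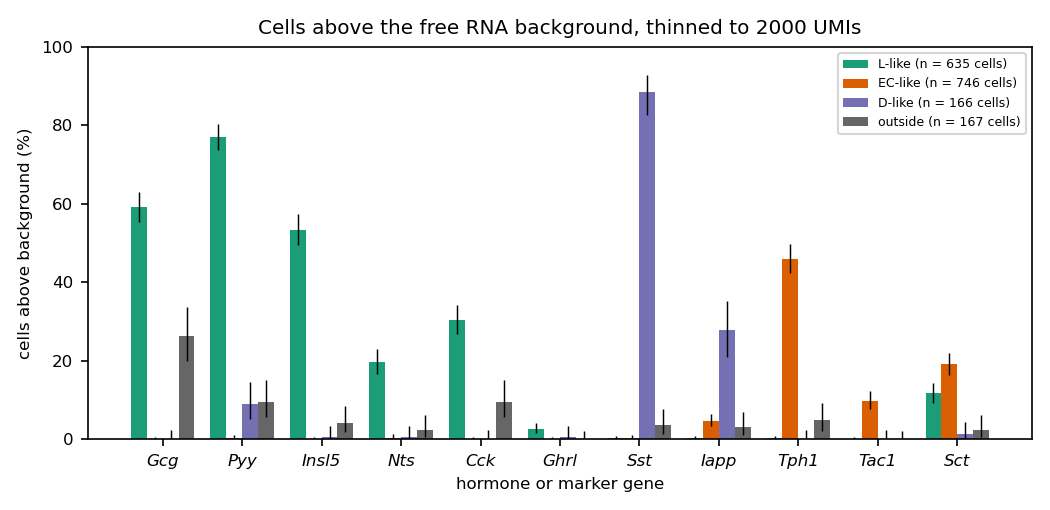
Percent of cells (y axis) above the free RNA background for each hormone or marker gene (x axis), in L-like (635), EC-like (746), D-like (166) and outside (167) cells thinned to 2000 UMIs, with exact 95% binomial intervals as bars. Gcg, Pyy and Insl5 mark L-like, Tph1 EC-like and Sst D-like cells, and Gcg also passes in 26.3% of outside cells.

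The main genes lie on GRCm38 as follows. Gcg (ENSMUSG00000000394) is on chromosome 2 at 62474530 to 62483650, Insl5 (ENSMUSG00000066090) on chromosome 4 at 103017872 to 103026842, and Sst (ENSMUSG00000004366) on chromosome 16 at 23889573 to 23890958. Tph1 (ENSMUSG00000040046) is on chromosome 7 at 46644641 to 46672537, as is Olfr558 (ENSMUSG00000070423) at 102702215 to 102712064. Slc38a11 (ENSMUSG00000061171) is on chromosome 2 at 65316430 to 65364034, Piezo2 (ENSMUSG00000041482) on chromosome 18 at 63010213 to 63387183 and Calcrl (ENSMUSG00000059588) on chromosome 2 at 84330626 to 84425411. Agtr1a (ENSMUSG00000049115) is on chromosome 13 at 30336441 to 30382867, Gpr119 (ENSMUSG00000051209) on chromosome X at 48667979 to 48674478 and Hoxb13 (ENSMUSG00000049604) on chromosome 11 at 96194316 to 96197447. The libraries read the 3' end of transcripts, and the table gives 1 count per gene.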

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

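No cell could be assigned to either sample, so leaving out a sample and the planned replicate models were not run. The share of EC-like cells was 39.1% under the stricter filter, which kept 1499 cells and removes shallow cells by construction, against 43.6% as reported. All other class shares stayed within their intervals. Under each alternative run, 54 of 54 named genes kept their direction between EC-like and L-like and 45 of 45 between D-like and L-like cells. Between L-like clusters 30 of 30 did, except at resolution 1.6, where 29 did and Mc4r turned to -0.53 on the log2 scale. The sizes of the ratios between L-like clusters were less stable. They moved for 15 of 30 genes at resolution 0.4 and with every barcode, 25 at resolution 1.6 and 17 under the UMI split. In the comparisons with EC-like and D-like cells, the sizes moved most under the other scaling, for 11 of 54 and 9 of 45 genes.

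With no minimum on UMIs, 45 list genes were higher in EC-like, 30 in D-like and 20 in the other L-like clusters, the nutrient receptor median was -0.54 and the median of all readout lists 0.56, since genes with a few UMIs then enter. With the scaling that leaves out hormone, granule, marker and abundant genes, the medians were 0.58 for ion channels, 0.29 for transcription factors, 0.13 for granule genes, 0.97 for amine genes and 0.26 for all lists, a shift that all 12825 genes share (0.32 to 0.12). The UMI split gave 0.75 for amine genes, 18 list genes higher in the Insl5-highest cluster and 20 in the others. The transporter median, whose interval spans 0, took either sign.

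The number of list genes higher in the Insl5-highest cluster, 6 as reported, was 17 at resolution 0.4, with 15 principal components and with every barcode, 0 at resolution 1.6, and 17 with both Insl5-high clusters joined, an alternative chosen after seeing the data. Which L-like cells share a cluster changes between these settings, and no further cause was tested.

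Co-detection moved with the threshold. Insl5 cells positive for Gcg were 97.9% at 2 UMIs, 71.0% at 20, 96.9% without thinning, 97.0% at 4000 UMIs, and 52.2% and 36.7% above 3 and 5 times the background, the last 2 thresholds chosen after seeing the data. In the same order, Insl5 cells positive for Nts were 69.4%, 0.66%, 17.4%, 20.3%, 1.15% and 0.68%. Gcg cells positive for Insl5 were 72.4% at 2 UMIs, 52.0% at 4000 UMIs and 32.0% above 5 times the background. Lower thresholds admit free RNA by construction. Depth limits genes with a few UMIs in the 166 D-like cells and any hormone below its background.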

Other observations

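Within the EC-like class, cluster 3 carried 12.2-fold more Olfr558 than the other EC-like clusters (8.74 to 17.3) and less Piezo2, at 20.4 against 306 counts per 1000000 UMIs (CPM). Clusters 4, 5 and 8 held Piezo2 at 407, 455 and 138 CPM and clusters 3, 7 and 12 at 20.4, 15.4 and 31.8. Cluster 7 held Sct at 47595 and Iapp at 2715 CPM, the first close to its level in L-like cluster 11, 54552. Clusters 4, 5 and 8 had Hoxb13 at 1533, 1084 and 1013 CPM, and clusters 3, 7 and 12 at 107, 105 and 117. These genes were chosen after their values were seen, and Sct and Iapp had entered the clustering.

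Tests of free RNA, stress, library differences and shared reads in this part were chosen after the results were seen, while those of mixed droplets and of a shared gene program were written before their values.

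Gcg exceeded background in 44 of 167 thinned cells outside the enteroendocrine classes (26.3%, 19.8 to 33.7), 36 of 123 in the unnamed cluster, 8 of 31 in the goblet-like and 0 of 13 in the stromal-like one. Free RNA alone would give a share near that of D-like cells, 0 of 166 (interval up to 2.20%), whose cells had not set the threshold, and the 26.3% argues against it as the whole cause. Droplets that hold an L-like cell beside another cell are a candidate explanation. Over 22 other L-like transcripts the median rise, relative to that of Gcg, was 0.94 (0.81 to 1.01), with Etv1 at 510 against 86.0 CPM. The Gcg-positive cells held a median of 15771 UMIs, against 13127 in the Gcg-negative outside cells and 7820 in L-like cells. Outside cells were thus deep with or without Gcg, so their depth says little about mixed droplets. No biological explanation was tested, as the design has no group for these cells.

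Hox genes divided L-like and EC-like clusters alike. Clusters 0 and 6 of the L-like and 4, 5 and 8 of the EC-like class were high in Hoxb13 (7.64-fold and 11.9-fold over the other clusters of their class) and low in Hoxb4 (23.6-fold and 37.2-fold) and Cdx2 (7.71-fold and 7.06-fold), genes chosen after their values were seen. Dissociation stress stays open, with a stress list median of 0.33 in each class but members that went both ways (in L-like cells from 2.83-fold for Dusp1 to 0.374 for Hspa1b), and a difference between both libraries cannot be told apart either, because cells carry no sample name and the background hormone that differed most, Sst at a ratio of 0.865, says little if both came from 1 suspension. Of 175 genes outside the lists that differed at least 4-fold between the L-like sets, 84.0% (77.7 to 89.1) went the same way in EC-like cells, against 58.4% of all 10701 genes, with Negr1 (20.1-fold and 72.0-fold) and Nxpe4 (16.8-fold and 41.3-fold) higher in the Hoxb13-high sets. As a hypothesis, a gene program shared by both classes, such as one that follows position along the large intestine, may underlie this, but the samples carry no position and no biological explanation from the design was tested.

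Ppy stood at 57940 CPM in L-like cluster 0 (76 cells), against 4111 in the other L-like clusters and 1248 in EC-like cells, and had entered the clustering. Pyy (chromosome 11, 102106676 to 102107832) lies 5357 bases from Ppy (102099930 to 102101319). Reads shared between these neighbours are argued against, since the ratio of Ppy to Pyy UMIs above background was 8.74-fold higher in that cluster, 27.2 against 3.11 Ppy per 100 Pyy UMIs. Free RNA is argued against by a level 46.4-fold above EC-like cells (44.9 to 48.0). No biological explanation was tested, as the design gives no group that separates these cells.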
